A study of Mus musculus with 4 samples.

How the data were processed

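Spiny projection neurons of the striatum were sorted by flow cytometry on EGFP from male mice aged 5 to 6 months, per the labels. Drd1-EGFP reporter mice gave the neurons of the direct pathway (D1) and Drd2-EGFP reporter mice those of the indirect pathway (D2). The mice were heterozygous zQ175 knock-in animals (Q175) or wild-type littermates (WT). Each of the 4 libraries came from a pool of 4 animals with 150000 cells per animal, per the series design text, so there was 1 library per group (D1 WT, D1 Q175, D2 WT and D2 Q175). Reads were paired and 50 nt long, sequenced at 4 samples per lane on an Illumina instrument.

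The deposited count table holds expected counts (estimated counts) per Ensembl gene that the authors left without normalization. This unit was read from the values, since 18.7% of them were not whole numbers and the columns had unequal totals. The deposited FPKM table holds FPKM, fragment counts scaled by the authors to transcript length and library size, per the file title. CASAVA 1.8.2 is named in the submitters' processing notes. The aligner, the counting program, the annotation release and the genome build are not given in the sources used here. Gene symbols were matched by Ensembl identifier for 32897 of the 37620 identifiers in the count table. Identifiers without a symbol held between 1.37% and 1.69% of the counts of a library. The GRCm38 reference annotation (GENCODE M21) was used for symbols, transcript length, GC content and the order of neighbouring genes, and no coordinate is given because the build behind the tables is unknown.

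Counts were rounded to whole numbers. Normalization factors came from the trimmed mean of M values (TMM) over all 4 libraries in edgeR 4.0.16 under R 4.3.3. Log2 ratios between 2 libraries were computed from normalized CPM (read counts scaled to library size) with a prior count of 2. Each ratio has a 95% exact conditional binomial interval. These intervals cover counting error alone, since reads without molecular identifiers are not independent molecules and no group had replicates. Total counts lay between 39444117 and 42787068 per library, so 1 normalized CPM stood for 38.2 to 43.8 counts, and 3 counts, the limit that a count of 0 allows, stood for 0.0685 to 0.0784 CPM. No p-value was computed between 2 single libraries. Such a difference is described by its size, and genes at least 2-fold apart were counted among those with a CPM of at least 5 in either library.

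A test was possible for effects shared by both cell types or by both genotypes. The edgeR quasi-likelihood test was fitted two-sided to all 4 libraries with cell type and genotype as additive terms, after filterByExpr, with Benjamini-Hochberg adjustment at 0.05. The fit leaves 1 residual degree of freedom. Its spread is the difference between the genotype effects of the cell types, but the spread is moderated across genes, so a gene that moved in only 1 cell type can also pass. A batch shared by both Q175 libraries would count as genotype, and the labels give no batch. Likewise, a difference between the Drd1-EGFP and Drd2-EGFP reporter mice, their pools or their sorts would count as cell type. The difference between the genotype effects of D1 and D2 neurons could not be tested and is given by size. The D1 and D2 genotype ratios share no library. Across genes, which are not replicates, their Pearson and Spearman correlations were computed, together with the number of genes at least 2-fold changed in both and the number that independent lists of those sizes would share.

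Gene lists of cell types, pathways and complexes (43 lists) and the rule for named genes were fixed before the data were examined. For lists with at least 4 members at a CPM of at least 1 in any library, the median log2 ratio was set against 10000 random lists of equal size matched on mean expression in 20 bins. Its percentile describes these libraries and is no p-value. A list lay outside the random range when its median was below percentile 2.5 or above 97.5. List members that passed the genotype test were counted after adjustment over all genes and after adjustment over the list alone. The rule named the 12 highest and 12 lowest ratios of each genotype comparison, and the 10 highest and 10 lowest of the cell type comparison in WT, among genes above the CPM minimum whose interval excluded 0. It also named the 10 smallest p-values in each direction of the shared genotype effect and the 8 largest differences in each direction between the genotype effects. Htt, the D1 and D2 neuron markers, the Kv4 channel complex and up to 4 members of each list outside the random range were always named, and unnamed gene models were skipped. This gave 157 genes, of which 62 had counts that were not whole. Any other gene named was chosen after its values were seen.

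The tests, the ratios and the list percentiles were tested on simulated counts before use. In the genotype test on 15726 simulated genes, 100% of genes changed 2-fold and 97% of genes changed 1.5-fold were called in the right direction, and 9 unchanged genes were called (4.37% of calls). In the cell type test on 15712 genes the shares were 100% and 93%, with 6 unchanged genes called (3.02% of calls). For a single pair of libraries with 10783 genes compared, 99.5% of 200 genes changed 3-fold passed the 2-fold rule and 0 unchanged genes did, and 95.1% of the counting intervals of unchanged genes held 0. Of 100 random lists, 4 lay outside the random range. In the simulations of the tests, libraries varied independently, by close to the residual biological coefficient of variation of the real libraries (6.80%). They held no batch and no genotype effect that differed between cell types. The single-pair simulation held counting noise alone, without differences between animals, pools or sorts. The rates above hold under these settings only.

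The alternatives were DESeq2 1.42.0 size factors, library totals alone, a CPM minimum of 1 or 20, a prior count of 0.5, and the deposited FPKM values with a pseudocount of 0.1 or 1 and a minimum FPKM of 1. For the tests they were the DESeq2 Wald test, no filter except genes with no count, a fit without the other factor, and limma 3.58.1 (limma-trend) on log2 FPKM. Random lists were also drawn from all measured genes. Leaving out any library leaves no residual degree of freedom and gives a value with no test. A loess correction (span 0.5) for transcript length and GC content, available for 97.8% of the compared genes, and a scaling without mitochondrially encoded genes were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Gpr52, Hmgcs1, Rpl24, Pde2a, Hoxd4, Slc18a3, Lhx8, Hbb-b1 and Hbb-b2 had no identifier matched in the count table and were not analysed here. Values of some single genes that counted toward the lists are not reported here.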

Results

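Gene expression was measured by RNA sequencing in sorted striatal spiny neurons of heterozygous zQ175 mice, which carry an expanded CAG repeat in Htt and model Huntington's disease, and of their wild-type littermates. Direct-pathway neurons (D1) were sorted on EGFP driven by a Drd1 reporter, and indirect-pathway neurons (D2) on EGFP driven by a Drd2 reporter. The groups D1 WT, D1 Q175, D2 WT and D2 Q175 held 1 library each, made from a pool of 4 animals. No group had replicates, so a difference between 2 libraries has no replicate check, and its interval covers counting error alone. Total counts were 39444117 in D1 WT, 40246718 in D1 Q175, 40957896 in D2 WT and 42787068 in D2 Q175. Levels are given as normalized CPM, read counts scaled to library size. Genes with at least 1 CPM numbered 12982, 13229, 13080 and 13284 in these libraries. Mitochondrially encoded transcripts took 6.06% of counts in D1 WT (exact 95% binomial interval 6.05 to 6.06%) and 8.98% in D1 Q175 (8.97 to 8.99%). Their share was 6.49% in D2 WT (6.48 to 6.49%) and 11.06% in D2 Q175 (11.05 to 11.07%).

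Htt (ENSMUSG00000029104), which carries the knock-in, stood at 159 CPM in D1 WT, 116 in D1 Q175, 154 in D2 WT and 121 in D2 Q175. Its log2 ratio of Q175 over WT was -0.46 in D1 (95% counting interval -0.52 to -0.41) and -0.35 in D2 (-0.40 to -0.29). In the fit to both cell types, Htt fell by 0.40 ± 0.08 log2 units (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00066; lower in both cell types). A knock-in allele is still transcribed and how the counting treated the altered exon is not given, so this level does not check the genotype labels.

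The difference between D2 and D1 neurons in WT checked the sort and described the cell types. D1 and D2 neurons came from different reporter mice, so cell type cannot be told apart from reporter line or pool. Drd2 (ENSMUSG00000032259), the dopamine receptor of the indirect pathway, stood at 2076 CPM in D2 WT and 8.58 CPM in D1 WT, 241-fold apart. Drd1 (ENSMUSG00000021478), the receptor of the direct pathway, stood at 1300 CPM in D1 WT and 33.0 CPM in D2 WT, a log2 ratio of -5.30 (-5.38 to -5.22). Adora2a, an adenosine receptor gene, was 277-fold higher in D2 WT, and Penk, which encodes the opioid precursor proenkephalin, was 88.7-fold higher. Pdyn, which encodes prodynorphin, stood at 273 CPM in D1 WT and 1.31 CPM in D2 WT, a log2 ratio of -7.66.

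All 7 measured D2 neuron markers were higher in D2 WT, with log2 ratios from 4.14 for Plxdc1 to 8.11 for Adora2a. All 9 D1 neuron markers were lower there, from -2.92 for Tac1, which encodes substance P, to -7.66 for Pdyn. Among the 10 genes highest in D2 WT were also the receptor gene Gpr6 (7.73), the kainate receptor gene Grik3 (6.96) and Nts, which encodes neurotensin (6.36, with 5 counts in D1 WT). Slitrk6 had 1 count in D1 WT and a log2 ratio of 6.08 (5.09 to 12.90). The list also held Ankk1 (7.29) and Ttc12 (6.96), which lie beside Drd2, and Upb1 (6.40), which lies beside Adora2a. Among the 10 lowest in D2 WT were also the transcription factor genes Isl1 (-6.80) and Ebf1 (-6.01), together with Sfxn1 (-6.34), the neighbour of Drd1, and Lingo2 (-5.53). Il20ra (-5.04), Slc35d3 (-4.97) and Npy (-4.44), which encodes neuropeptide Y, were in the same group.

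Immediate early genes, which neuronal activity induces, were higher in D2 WT than in D1 WT, with a median log2 ratio of 0.39 at percentile 100 of random lists. The members Jun (0.87) and Fos (0.74) were among them, and Homer1 (-0.47) ran the other way. Unfolded protein response genes had a median of -0.25 and heat shock and chaperone genes a median of -0.33, both at percentile 0. Microglia markers (median 0.55, percentile 99.8), oligodendrocyte markers (0.39, percentile 99.5) and astrocyte markers (0.27, percentile 98.8) were also higher in D2 WT. These medians kept their sign under every scaling tried. Whether they reflect cell type, reporter line, pool or sort was not tested.

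Of 10838 genes compared in WT, 94 were at least 2-fold higher in D2 and 134 at least 2-fold lower. In Q175 the counts were 84 and 119 of 11000. In the fit to both genotypes, 1052 genes were higher in D2 and 1051 lower among 15668 tested, and of these 228 and 256 were at least 2-fold apart. Adora2a was higher in D2 by 8.33 ± 0.14 log2 units (SE; edgeR, adjusted p = 2.5e-23; in both genotypes). An unadjusted p under 0.05 was found for 4140 genes. With the DESeq2 Wald test the counts were 382 and 495, and without filter 286 and 377.

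**Figure D1:**
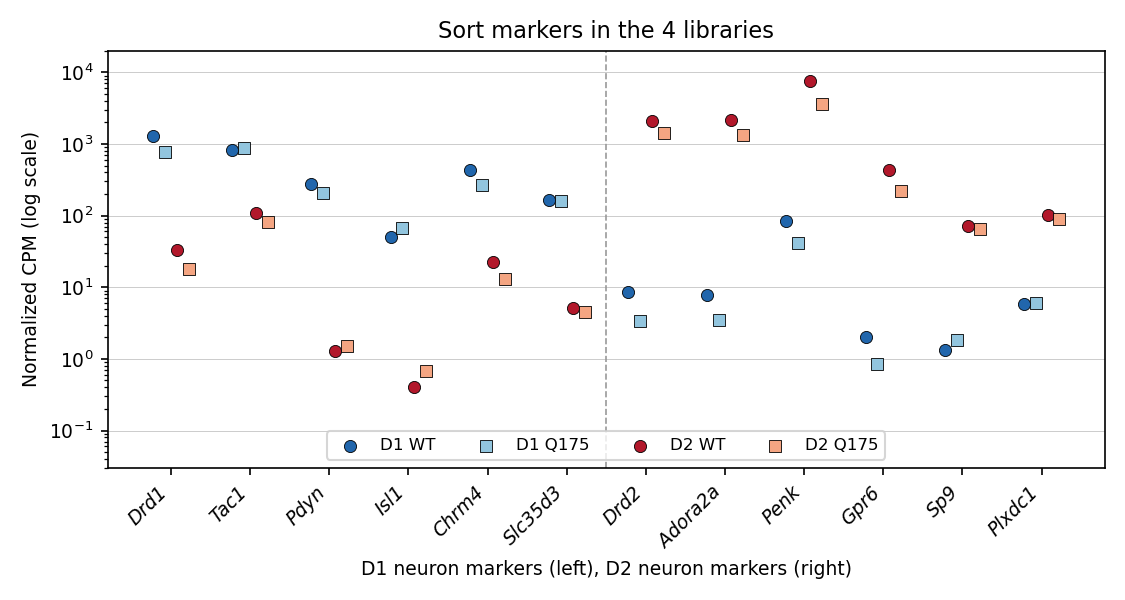
Normalized CPM on a log axis of 6 D1 neuron markers (left) and 6 D2 neuron markers (right), each point 1 library, with circles for WT and squares for Q175. Drd1 stood at 1300 CPM in D1 WT and 33.0 CPM in D2 WT, and Drd2 at 8.58 and 2076 CPM.

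The comparison of Q175 with WT in D1 neurons asked how the knock-in changes direct-pathway neurons. Ddit4l (ENSMUSG00000046818), whose product restrains mTOR signalling, was 5.57-fold lower in D1 Q175, from 56.6 to 10.1 CPM. Wnt4, a secreted signalling ligand, was 6.65-fold lower, from 6.96 to 1.01 CPM. The highest ratio was that of Sfmbt2, a Polycomb-group gene, with a log2 ratio of 4.84 (4.13 to 6.35) from 8 counts in D1 WT and 306 in D1 Q175. Nrbp2 (ENSMUSG00000075590), which encodes a pseudokinase, was 4.73-fold higher, from 7.58 to 36.0 CPM.

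Other genes among the 12 highest were Cntrl, a centrosome gene (log2 ratio 2.48), and the desmosomal cadherin gene Dsg2 (2.09). The list went on with Fbn1, which encodes fibrillin (2.07), Rprm (1.91), Asap3 (1.91), Olfm2 (1.88), Echdc2 (1.78), Cacna1g, a T-type calcium channel gene (1.77), and Vwa5b2 (1.72). Among the 12 lowest were the copine gene Cpne9 (-2.34), the glutathione peroxidase gene Gpx6 (-2.24) and Tmprss6 (-1.92). Sec14l3 (-1.89), Shisa2 (-1.78), Il17rc (-1.77), Phex (-1.68), B3gnt2 (-1.64), Clspn, a gene of the replication checkpoint (-1.63), and Slc4a11 (-1.59) completed them. Of the D1 neuron markers, Sfxn1 (-0.77), Drd1 (-0.75), Chrm4, a muscarinic receptor gene (-0.70), and Pdyn (-0.42) were lower in D1 Q175. Isl1 (0.43), Eya1 (0.25) and Tac1 (0.11) were higher. The median of the 9 markers was -0.03, at percentile 52.1 of random lists, and became 0.07 when scaled by library totals or with FPKM.

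In D1 neurons, 122 genes were at least 2-fold higher and 77 at least 2-fold lower among 10926 compared. Higher genes made up 61.3% of these. With a CPM minimum of 20 the counts were 28 and 35, or 44.4% higher. When scaled by library totals the counts were 159 and 54, or 74.6% higher, and the median ratio of all genes moved by 0.10. With FPKM and a pseudocount of 0.1 the counts were 325 and 125 (72.2% higher), the shift was 0.11, and changes are given relative to the TMM scale.

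The same comparison in D2 neurons addressed the indirect pathway. Ddit4l was 5.35-fold lower in D2 Q175, from 31.1 to 5.78 CPM, and Phex, a metallopeptidase gene, had a log2 ratio of -2.27, from 20.1 to 4.11 CPM. Cacna1g was 8.44-fold higher, with a log2 ratio of 3.08 (2.70 to 3.58), and Nrbp2 was 5.42-fold higher. Penk was lower by more than any other D2 neuron marker, from 7476 to 3582 CPM.

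The 12 highest genes in D2 neurons also held Kazald1 (log2 ratio 2.55), Tmem255a (2.46), the protocadherin gene Pcdh20 (2.30), Sfmbt2 (2.13), Fam126a (2.10) and Trp53i11 (2.02). Olfm2 (1.98), the receptor kinase gene Ltk (1.97), Stmn2, which encodes a tubulin-binding protein (1.97), and the ceramide synthase gene Cers2 (1.97) completed them. The 12 lowest included Wnt4 (-2.09), Plekhg4 (-1.96), Gpx6 (-1.92), Il17rc (-1.89), Cpne9 (-1.88) and Shisa2 (-1.74). Htr1b, a serotonin receptor gene (-1.65), Ankrd35 (-1.67), Tnfrsf25 (-1.63) and Tmprss6 (-1.59) were the others. All 7 D2 neuron markers had lower values in D2 Q175: Penk (-1.06), Gpr6 (-0.99), Adora2a (-0.70), Drd2 (-0.53), Ttc12 (-0.25), Plxdc1 (-0.22) and Sp9 (-0.15). Their median of -0.53 lay at percentile 0.08 of random lists.

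Counts in D2 neurons were 148 genes at least 2-fold higher and 116 at least 2-fold lower of 10961 compared, or 56.1% higher. With a CPM minimum of 20 they were 37 and 52, or 41.6% higher, and scaled by library totals 188 and 89, or 67.9% higher. FPKM gave 398 and 195 (67.1% higher) with a pseudocount of 0.1 and 150 and 72 (67.6%) with 1.

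The shared genotype effect asked which genes changed on average over D1 and D2 neurons. Ddit4l fell by 2.45 ± 0.11 log2 units (SE; edgeR, adjusted p = 1.7e-13; lower in both cell types), and Nrbp2 rose by 2.35 ± 0.11 (adjusted p = 6.7e-13; higher in both). Ryr1, which encodes a calcium release channel, fell 2.77-fold, from 425 to 159 CPM in D1 and from 317 to 110 CPM in D2. Of 15668 genes tested, 2159 rose and 2192 fell (27.8% passed), and at least 2-fold changes numbered 559 upward and 198 downward. A gene list in which a share near or below 27.8% passed is therefore not set apart by its count. The residual biological coefficient of variation was 6.80%.

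The other genes with the smallest p among those that fell were B3gnt2 (-1.60 log2 units), Cpne9 (-2.12), Clspn (-1.55), the kinase gene Plk5 (-1.28), Shisa2 (-1.76), Phex (-1.94), Plekhg4 (-1.65) and Gpx6 (-2.06). Those that rose were Vwa5b2 (1.79), Olfm2 (1.95), Echdc2 (1.88), Tbkbp1 (1.39), Cntrl (2.14), Cers2 (1.72), Fam126a (1.90), Kndc1 (1.52) and Ece2 (1.18). All 20 genes named by p were called by DESeq2, by limma on FPKM and without filter. Without cell type in the model, 4 genes were called, namely B3gnt2, Nrbp2, Vwa5b2 and Clspn. The DESeq2 Wald test called 749 genes higher and 1239 lower (37.7% higher), limma on FPKM with a pseudocount of 0.1 called 2210 and 1123 (66.3% higher), and the share in edgeR was 49.6%. An unadjusted p under 0.05 was found for 6009 genes.

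Genes that mark spiny neurons of both pathways fell together. Of 30 tested, 28 fell and 0 rose after adjustment over all genes, and 28 fell when adjusted over the list alone. The exceptions, Foxp2 (0.07 ± 0.08) and Gng7 (-0.19 ± 0.09), did not pass. Pde10a, the striatal phosphodiesterase gene, stood at 2188 CPM in D1 WT and 1095 in D1 Q175, and at 2517 CPM in D2 WT and 989 in D2 Q175. Cnr1, the cannabinoid receptor gene, fell by 1.26 ± 0.10 log2 units, Scn4b, a sodium channel subunit gene, by 1.24 ± 0.10, and Rgs14 by 1.05 ± 0.08. The median log2 ratio of the list was -0.63 in D1 and -0.64 in D2, both at percentile 0 of random lists, whose middle 95% ran from -0.29 to -0.08 in D1 and from -0.30 to -0.08 in D2. Of the striosome markers 4 of 7 fell and 0 rose, with medians of -0.23 in D1 (percentile 2.92, inside the random range) and -0.33 in D2 (percentile 0.59). They were Kremen1 (-0.50 ± 0.08), Bach2 (-0.38 ± 0.12), Khdrbs3 (-0.30 ± 0.09) and Sema5b (-0.29 ± 0.09). Of the matrix markers 3 of 6 fell and 0 rose, namely Epha4 (-0.30 ± 0.08), Id4 (-0.54 ± 0.08) and Cntnap3 (-1.38 ± 0.14), with medians of -0.24 and -0.23, inside the random range (percentiles 7.20 and 10.3). Adjusted over the list alone, the counts that fell were again 4 for striosome and 3 for matrix markers.

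Among D2 neuron markers, 4 of 7 fell and 0 rose in the shared fit, the same counts when adjusted over the list alone, with Penk at -1.03 ± 0.10, Gpr6 at -1.02 ± 0.11, Adora2a at -0.83 ± 0.11 and Drd2 at -0.77 ± 0.13. These estimates include the D1 libraries, where Drd2, Adora2a and Gpr6 stayed under 9 CPM and the list median was -1.01 (percentile 0), and Drd2 had a log2 ratio of -1.33 in D1 against -0.53 in D2. Of 9 D1 neuron markers, 4 fell and 2 rose, again the same counts when adjusted over the list alone. Drd1 fell by 0.80 ± 0.09, Chrm4 by 0.72 ± 0.09 and Sfxn1 by 0.61 ± 0.10, while Isl1 rose by 0.47 ± 0.12 and Eya1 by 0.48 ± 0.17. Pdyn passed as lower, but its log2 ratio was -0.42 in D1 and 0.22 in D2, where it had 1.31 and 1.53 CPM. The median of the D1 neuron markers in D2 neurons was -0.40 (percentile 0.26).

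Immediate early genes mostly fell. Of 21 tested, 14 fell and 4 rose, and 14 and 4 did so adjusted over the list alone. The early growth response gene Egr2 fell by 1.16 ± 0.09 log2 units and Jun by 1.33 ± 0.14. Egr1 (-0.71 ± 0.09) and Egr3 (-1.09 ± 0.10) fell too, and Fos (0.50 ± 0.09), Btg2 (0.37 ± 0.12), Nr4a2 (2.77 ± 0.35) and Atf3 (1.83 ± 0.27) rose. Nr4a2 and Atf3 stayed under 4 CPM in all libraries. The list median was -0.49 in D1 and -0.38 in D2, both at percentile 0.

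Of the genes of protein folding, more fell than rose. In the unfolded protein response list 10 of 17 fell and 0 rose, likewise adjusted over the list alone, with medians of -0.44 in D1 (percentile 0) and -0.29 in D2 (percentile 0.19). The sensor gene Atf6 fell by 0.89 ± 0.09, the chaperone gene Hspa5 by 0.53 ± 0.08 and Pdia4 by 0.52 ± 0.09. In the heat shock and chaperone list 7 of 17 fell and 1 rose, Bag3 (1.41 ± 0.39), a co-chaperone gene under 1 CPM in all libraries. Adjusted over the list alone, 9 fell and 3 rose. Dnaja1 fell by 0.40 ± 0.08, and the list median was -0.30 in D1 (percentile 0.83) and -0.17 in D2 (percentile 23.4).

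Ion channel and synapse genes fell more often than they rose. Of 16 potassium channel genes of the inward rectifier, Kv1, Kv7 and background families, 10 fell and 1 rose, as they did adjusted over the list alone, with medians of -0.32 in D1 and -0.31 in D2. Kcnab1 fell by 0.80 ± 0.09 and Kcnj4 by 0.58 ± 0.08, and Kcnj3 (0.42 ± 0.13) rose. In the Kv4 channel complex 3 of 9 fell and 2 rose, also when adjusted over the list alone. The subunit genes Kcnip2 (-0.34 ± 0.09), Kcnd2 (-0.31 ± 0.08) and Kcnip3 (-0.28 ± 0.08) fell, and Dpp10 (0.49 ± 0.09) and Kcnip1 (1.02 ± 0.31) rose. The Kv4 list medians, -0.16 and -0.21, lay inside the random range. Of 19 postsynaptic scaffold genes 11 fell and 2 rose, with medians of -0.33 and -0.34 at percentiles 0.14 and 0.25. Homer1 fell by 0.99 ± 0.08 and Dlg2 by 0.82 ± 0.08, and Shank1 (0.55 ± 0.13) and Homer2 (0.48 ± 0.18) rose. Scaffold counts were the same when adjusted over the list alone. Of 29 genes of cAMP and G protein signalling 15 fell and 2 rose (16 and 3 adjusted over the list alone), with Adcy9, an adenylyl cyclase gene, at -0.93 ± 0.13 and Rgs4 at -0.94 ± 0.09. The genes that rose were Pde1a (1.12 ± 0.20) and Gnas (0.56 ± 0.09), whose count is uncertain because other transcripts overlap it. In the neurotrophin list 5 of 13 fell and 1 rose (8 and 1 adjusted over the list alone), with Ntrk3 at -0.62 ± 0.10 and Shc1, the gene that rose, at 0.45 ± 0.13. The signalling medians were -0.23 in D1 and -0.26 in D2 for cAMP and G protein genes, and -0.27 and -0.21 for neurotrophin genes. These lists overlap with those above, so their counts are not independent results. Rgs4, Rgs9, Ppp1r1b, Pde1b, Pde10a, Adcy5, Gnal and Ptpn5 of the cAMP list also fell as members of the spiny neuron identity list. Kcnab1 and Kcnj4 of the potassium channel list belong to it too, and Homer1 counted in both the scaffold and immediate early lists.

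Mitochondrially encoded genes rose. Of 15 tested, 14 rose and 0 fell, and 15 rose when adjusted over the list alone. The median log2 ratio was 0.44 in D1 and 0.67 in D2, both at percentile 100, and mt-Co1, a subunit gene of cytochrome c oxidase, rose by 0.68 ± 0.12. After correction for transcript length and GC content the medians were 0.27 in D1 and 0.51 in D2. Nuclear genes of oxidative phosphorylation changed less. Of 55, 1 rose (Cox6c, 0.23 ± 0.08) and 5 fell (0 and 2 adjusted over the list alone), with Cox5a at -0.36 ± 0.08 and Sdha at -0.33 ± 0.08, and the medians were -0.11 in D1 (percentile 23.0) and 0.06 in D2 (percentile 100). Against random lists from all measured genes the D2 percentile was 94.1. The D1 value became 0.004 with FPKM, and the D2 value -0.01 after correction for transcript length and GC content. Of 53 cytosolic ribosomal protein genes 8 rose and 2 fell, Rpl4 (-0.32 ± 0.08) and Rpl10a (-0.24 ± 0.09). Adjusted over the list alone, 5 rose and 1 fell. Their median was 0.29 in D2 (percentile 100) and 0.01 in D1 (percentile 99.6, but 69.5 against random lists from all measured genes), and these medians became 0.15 in D2 and -0.03 in D1 after correction for transcript length and GC content. Across genes, which are not independent replicates, the deviation of the D2 Q175 library from the others had a Spearman correlation of -0.26 with transcript length and 0.19 with GC content. In the other libraries these lay between 0.02 and 0.16 for length and between -0.18 and 0.05 for GC content.

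Markers of other cell types were mostly low and partly higher in Q175. In D1 WT the median level was 2.09 CPM for oligodendrocyte and 3.65 CPM for astrocyte markers. Single markers stood far higher there, such as Mbp at 247 CPM and Slc4a4 at 278 CPM. Of 12 oligodendrocyte markers 7 rose and 0 fell, also when adjusted over the list alone, with medians of 0.43 in D1 (percentile 98.8) and 0.55 in D2 (percentile 99.5). Mag rose by 0.77 ± 0.19, from 1.60 to 2.49 CPM in D1 and from 3.42 to 6.14 CPM in D2. Astrocyte markers had 3 of 12 rise and 2 fall, also when adjusted over the list alone, with medians of 0.16 in D1 and 0.32 in D2. Slc1a3 (0.45 ± 0.10), Aldoc (0.35 ± 0.09) and Fgfr3 (0.84 ± 0.19) rose, and Slc4a4 (-0.41 ± 0.09) and Atp1b2 (-0.82 ± 0.09) fell. Fgfr3 is also among the 40 nearest tested genes around Htt, which are described at the end. Of 14 microglia markers 2 rose, Cx3cr1 (0.76 ± 0.23) and Csf1r (0.49 ± 0.13), and 0 fell, the same counts when adjusted over the list alone, with medians of 0.48 in D1 (percentile 95.4) and 0.33 in D2 (percentile 79.1). Of 7 markers of cortical excitatory neurons 2 rose and 0 fell, also when adjusted over the list alone. Cux2 (1.26 ± 0.16), which was under 8 CPM in all libraries, was among those that rose. The clustered protocadherin beta genes, which encode cell adhesion molecules, had 7 of 20 rise and 0 fall, also when adjusted over the list alone, with Pcdhb3 at 1.04 ± 0.15 and list medians of 0.31 and 0.34. Reads of these near-identical paralogs are uncertain, because the counting could split them.

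**Figure D2:**
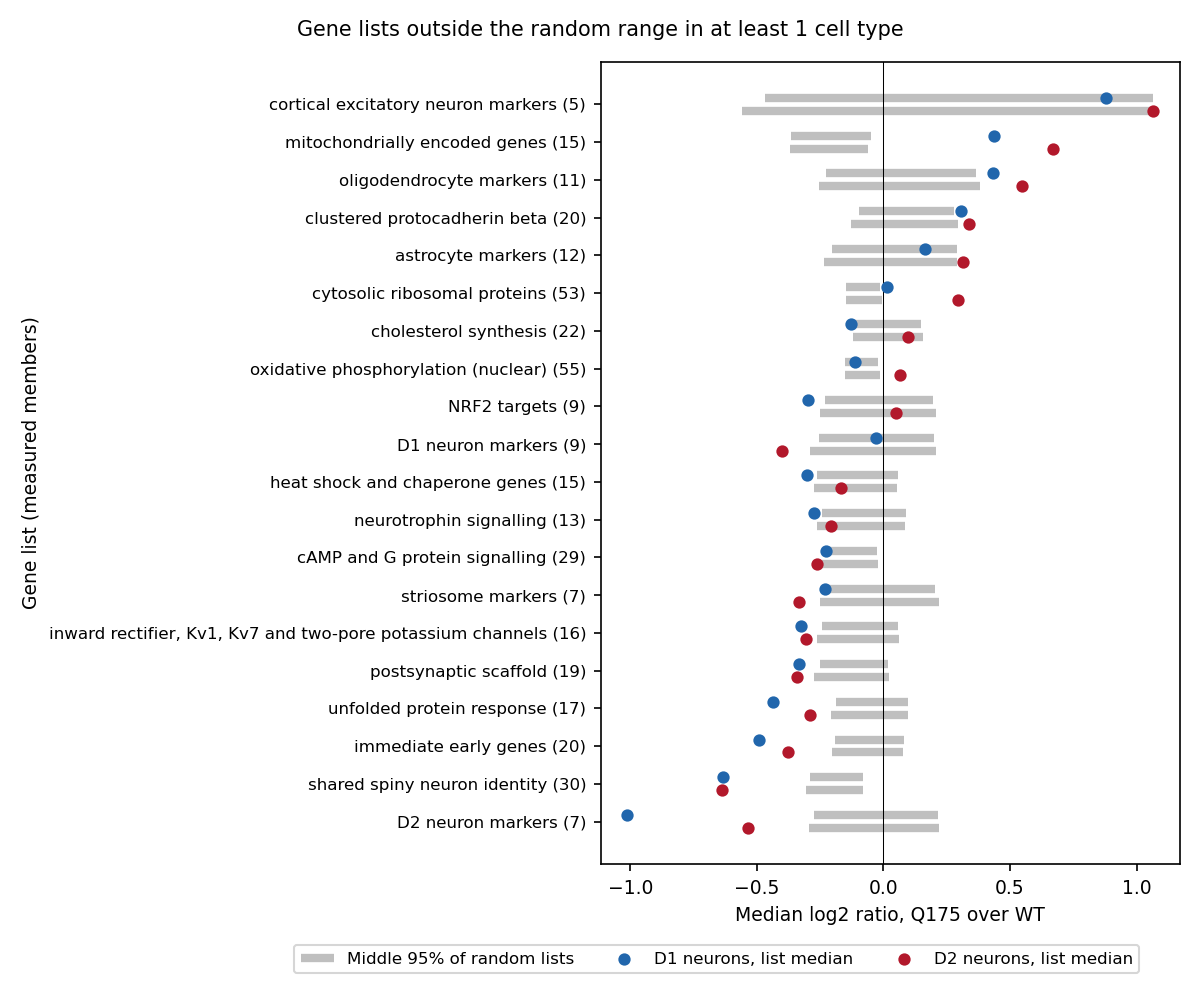
Median log2 ratio of Q175 over WT for each gene list that lay outside the random range in D1 (blue) or D2 (red), with the number of measured members and grey bars for the middle 95% of 10000 random lists. The identity list stood at -0.63 and -0.64 and the mitochondrially encoded genes at 0.44 and 0.67, while medians near 0 (D1 neuron markers, ribosomal, oxidative phosphorylation, NRF2 and cholesterol lists) changed sign with another scaling, FPKM or the length and GC correction in at least 1 cell type.

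The genotype ratios of the cell types were then set against each other. Over 11152 genes, which are not replicates, they had a Pearson correlation of 0.79 and a Spearman correlation of 0.73. Genes at least 2-fold higher numbered 141 in D1 and 166 in D2, and 89 were shared where independent lists would share 2.10. Genes at least 2-fold lower numbered 80 and 131, and 51 were shared against 0.94. No gene was 2-fold changed in opposite directions, and 370 of 378 genes that were 2-fold changed in either cell type (97.9%) had the same sign in both. The ratios share no library, and the labels give no batch by which to separate the Q175 libraries from the WT libraries.

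Differences between the genotype ratios of D1 and D2 neurons were not tested. The log2 ratio of Cacna1g was larger in D2 by 1.31, with 3.08 in D2 and 1.77 in D1. Trp53i11 (1.34), Igsf21 (1.19) and Mast4 (1.14) were also larger in D2, as were Rps27rt (1.79), Xlr3b (1.45) and Tpt1-ps3 (1.19), whose reads are uncertain because each has near-identical copies. In the other direction stood Sfmbt2 (-2.71), Ebf1 (-1.68), which had 0.45 CPM in D2 WT, Fbn1 (-1.64), and Chrd, which encodes the secreted antagonist chordin (-1.56). Thpo (-1.43), Mid1 (-1.28), Cdr1 (-1.21) and Alk (-1.14) completed the 8. Mid1 passed the shared test as higher (0.57 ± 0.16), yet its log2 ratio was 1.23 in D1 and -0.05 in D2. Of 11152 genes compared, 22 had a ratio at least 2-fold larger in D2 and 17 at least 2-fold smaller, and the SD of the difference was 0.24. With FPKM and a pseudocount of 0.1 these counts were 131 and 161, or 44.9% larger in D2 against 56.4%.

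**Figure D3:**
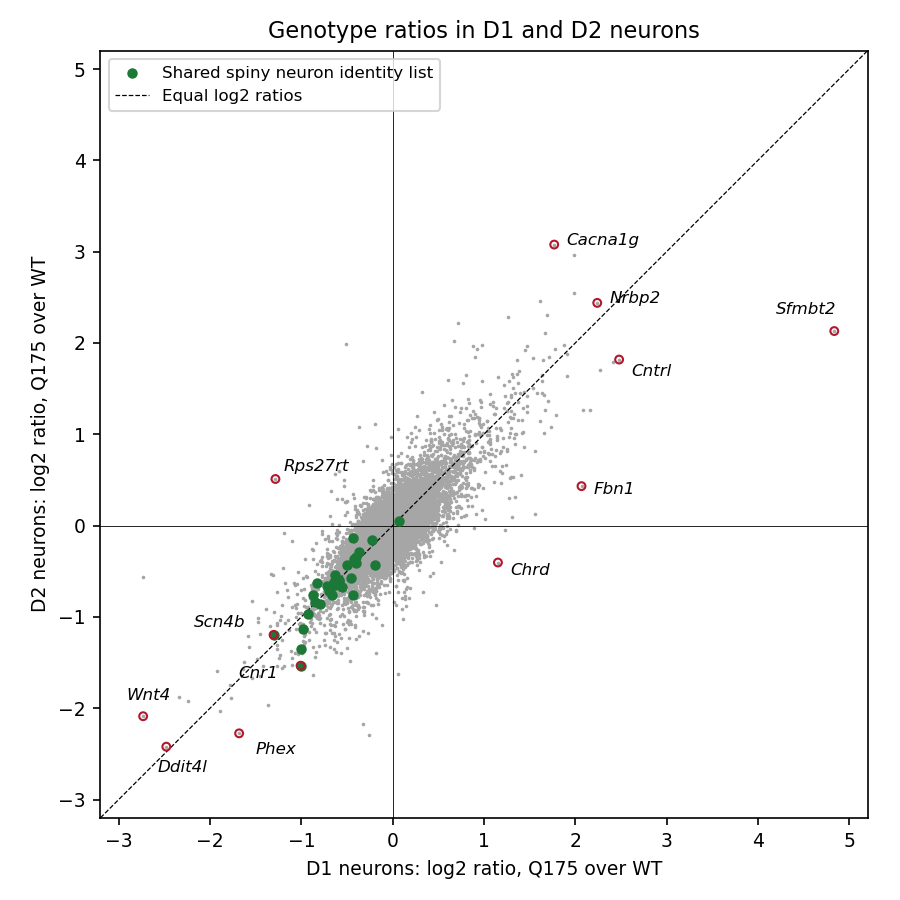
Log2 ratio of Q175 over WT in D2 neurons against that in D1 neurons, each grey point 1 gene, with the shared spiny neuron identity list in green, named genes circled and a dashed line at equal ratios. The Pearson correlation over 11152 genes was 0.79, and of the identity list only Foxp2 lay above 0 in both cell types.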

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

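The differences below were singled out because the genotype ratio pointed one way in D1 neurons and the other way in D2 neurons, with counting intervals that excluded 0 on both sides. None of these differences was tested, since each ratio rests on 1 library per group. Each value is the log2 ratio of Q175 over WT in D2 minus that in D1.

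Chrd had a difference of -1.56, with a log2 ratio of 1.15 in D1 and -0.40 in D2. Grik3, which marks D2 neurons, had 0.52, from -0.40 in D1, where it stood at 2.95 CPM in WT, and 0.12 in D2. For Igsf21 the difference was 1.19, with -0.63 in D1 and 0.56 in D2. Tac1, a D1 neuron marker, had -0.54, with 0.11 in D1 and -0.43 in D2. The values of Rps27rt (1.79), Xlr3b (1.45) and Tpt1-ps3 (1.19) rest on reads shared with near-identical copies, and their counts were not whole, so the genes behind them are uncertain.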

How the results depend on the processing

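Values with no test were compared with their counting interval, counts with a factor of 1.5, and tests with their threshold. For named genes, 2701 of 3427 alternative values kept their call or stayed within the interval, 485 moved beyond the interval, 228 lost the test, 8 gained it and 5 changed direction. For gene lists outside the random range, 109 of 120 alternative percentiles stayed outside and 11 moved inside, and for the other lists 173 of 184 stayed inside and 11 moved outside. Corrections for transcript length and GC content and the scaling without mitochondrially encoded genes were chosen after seeing the data. Leaving out any library left no residual degree of freedom, so those values have no test: for named genes, the shared effect lay within the counting interval of the remaining ratio in 374 of 628 values and outside it in 250, and 4 changed direction. Leaving out either library of a cell type leaves the same ratio, so these values repeat, and the 4 belong to Pdyn and Mid1. The remaining ratio is also part of the shared effect that it was set against. No pairing by animal was possible because each group held 1 pooled library. The genotype test compared Q175 with WT within cell type through its additive term.

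With a CPM minimum of 1, genes at least 2-fold higher and lower numbered 383 and 154 in D1, 458 and 232 in D2, 194 and 255 between cell types in WT, 206 and 227 in Q175, and 115 and 112 for the difference between genotype ratios. With a CPM minimum of 20 they were 28 and 35, 37 and 52, 43 and 63, 36 and 49, and 7 and 6. With FPKM and a pseudocount of 0.1 they were 325 and 125, 398 and 195, 189 and 212, 191 and 204, and 131 and 161. With FPKM and a pseudocount of 1, the genes lower in D2 numbered 72, and the difference counts were 58 and 55. After correction for transcript length and GC content, 11 genes had a smaller ratio in D2. The Pearson correlation of the genotype ratios was 0.73 with a CPM minimum of 1, 0.60 with FPKM and a pseudocount of 0.1, and 0.81 after correction for transcript length and GC content. The cause was not tested.

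Genes called higher and lower for genotype numbered 749 and 1239 with the DESeq2 Wald test, 1002 and 1180 with no filter, and 2 and 2 without cell type in the model, where cell type differences enter the spread. limma-trend on FPKM called 1123 lower with a pseudocount of 0.1 and 1143 with 1. For cell type they numbered 382 and 495 with the Wald test, 286 and 377 with no filter, and 32 and 45 without genotype in the model. limma-trend called 619 and 689 with a pseudocount of 0.1, and 635 higher with 1. Of 1988 genotype calls of the Wald test, 1987 were shared with the 4351 of edgeR in the same direction. For limma-trend with a pseudocount of 0.1, 2609 of 3333 were shared, and after correction for transcript length and GC content 4046 of 4987. Except as stated, the cause was not tested.

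Pdyn changed direction when a library was left out, with a range of -0.42 to 0.22, and so did Mid1, with -0.049 to 1.23. For these the D1 and D2 ratios differed in sign. Dpp6 in D1 became 0.00225 when scaled by library totals, 0.00226 with FPKM and a pseudocount of 0.1, and 0.00223 with a pseudocount of 1. Txnrd1 in D2 became 0.000418 with FPKM and a pseudocount of 0.1, and 0.000405 with 1. Both lay near 0, at -0.10 and -0.08, and these settings moved the median ratio of all genes by 0.08 to 0.11.

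Percentiles that moved inside the random range were the astrocyte list in D2 at 96.4 with FPKM, and the cortical excitatory list in D2 at 97.3 with library totals, 91.985 with FPKM and 96.6 after correction for transcript length and GC content. The cholesterol list in D1 moved to 5.15 against random lists from all measured genes and 9.27 with FPKM. Against random lists from all measured genes, oxidative phosphorylation in D2 moved to 94.1 and ribosomal proteins in D1 to 69.5. The neurotrophin list in D1 moved to 9.71 with FPKM and 3.16 after correction for transcript length and GC content, and the cAMP list in D2 to 2.94 with FPKM. The cause was not tested.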

Other observations

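Other receptor and channel genes changed in the shared genotype fit, in which 27.8% of all tested genes passed. In this section, counts near or below that share do not set a list apart from genes in general. Of 23 sodium and calcium channel genes, 10 fell and 1 rose, Cacna1g (11 and 1 adjusted over the list alone), with Cacna1e at -0.76 ± 0.10 log2 units and Cacnb1 at -0.56 ± 0.08. Scn4b, which is also on the spiny neuron identity list, was among those that fell. Of 21 glutamate receptor genes, 6 fell and 1 rose (8 and 3 adjusted over the list alone). Grin2a fell by 0.78 ± 0.19, and Grik4 rose by 1.02 ± 0.18. Of 18 genes of GABA receptors and synthesis, 4 fell and 1 rose (5 and 1 adjusted over the list alone). Gabrd (-0.83 ± 0.09), Gabra4 (-0.42 ± 0.08), Slc32a1 (-0.39 ± 0.09) and Gabbr1 (-0.28 ± 0.09) fell, and Gabrg1 rose by 1.57 ± 0.19. The medians of these 3 lists lay inside the random range in both cell types.

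In glycolysis, 6 of 15 genes fell and 1 rose (7 and 1 adjusted over the list alone), with Tpi1 at -0.36 ± 0.09, Eno1 at -0.34 ± 0.09 and Pfkl at 0.31 ± 0.09. Of 22 cholesterol synthesis genes 4 fell and 4 rose, also when adjusted over the list alone. Acat2 (-0.54 ± 0.09), Msmo1 (-0.48 ± 0.09) and Srebf2 (-0.43 ± 0.08) were among those that fell, and Mvk (0.47 ± 0.13), Dhcr7 (0.44 ± 0.11), Pmvk (0.35 ± 0.11) and Sc5d (0.29 ± 0.11) rose. In the autophagy and lysosome list 4 of 26 fell and 2 rose, likewise adjusted over the list alone, with Gabarapl1 at -0.31 ± 0.09, Pik3c3 at -0.29 ± 0.09, Ctsb at -0.29 ± 0.09 and Atg9a at -0.24 ± 0.08, against Ulk1 at 0.26 ± 0.08 and Optn, which was below 1 CPM in every library, at 1.88 ± 0.53. Of 31 proteasome genes 2 fell, Psmd7 and Psmd13 (0 adjusted over the list alone). Of 13 targets of p53, 4 fell and 3 rose (5 and 3 adjusted over the list alone), with Gadd45a at -1.50 ± 0.20, Zmat3 at -0.32 ± 0.08, Sesn1 at -0.26 ± 0.08 and Plk2 at -0.23 ± 0.09, against Bax at 0.31 ± 0.09, Sesn2 at 0.44 ± 0.15 and Phlda3, also below 1 CPM in every library, at 1.19 ± 0.38; Cdkn1a (-0.36 ± 0.15) was the addition within the list. In the interferon list Ifi27 fell by 0.55 ± 0.17 of 10 tested, also adjusted over the list alone. In the NRF2 list Gsr fell by 0.25 ± 0.09 of 10 tested (0 adjusted over the list alone).

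Among 30 Polycomb and chromatin modifier genes, 4 rose and 2 fell (4 and 1 adjusted over the list alone). Hdac1 rose by 1.37 ± 0.11, Cbx8 by 0.82 ± 0.11 and Kdm6b by 0.31 ± 0.09, and Hdac4 fell by 0.71 ± 0.17 and Tet3 by 0.22 ± 0.08. Of 49 developmental regulators silenced by Polycomb, only 5 passed the filter and were tested. Of these, 3 rose (4 adjusted over the list alone), namely Wt1, Pax6 (0.56 ± 0.20) and Onecut2 (0.25 ± 0.08). A gene nearly silent in WT can enter the test only through its Q175 counts, so the filter favoured genes that rose. Wt1 had 3 counts in each WT library and reached 1.87 CPM in D1 Q175 and 1.60 CPM in D2 Q175. The tested Hox gene, Hoxa7, rose by 1.58 ± 0.42. Of 9 polyglutamine disease genes 2 fell, Atxn1 (-0.85 ± 0.13) and Htt, also when adjusted over the list alone. Of 10 genes of mismatch repair and repeat maintenance 2 rose, among them Rrm2b (0.24 ± 0.09), and 0 did so adjusted over the list alone.

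Low-level markers of other cells moved in mixed directions. Of 5 oligodendrocyte precursor markers 2 rose, Olig1 (0.69 ± 0.20) and Pdgfra (1.39 ± 0.35), also when adjusted over the list alone. Of 6 GABA interneuron markers 2 rose, Cck (0.73 ± 0.23) and Th (1.43 ± 0.38), and 2 rose and 2 fell adjusted over the list alone. In the mural list Vtn (1.08 ± 0.27) rose and Tagln (-0.83 ± 0.16) fell of 7 tested, likewise adjusted over the list alone. Of 10 endothelial markers Esam (-0.41 ± 0.13) fell, and 0 did so adjusted over the list alone. No ependymal, red blood cell or cholinergic marker passed in edgeR, of 3, 3 and 2 tested, while 1 cholinergic marker, Slc5a7, passed as higher adjusted over the list alone.

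Of the tests that follow, the comparison of genes beside Drd1 and Drd2 and both tests of a lower share of spiny neurons were chosen after the result was seen. The others were chosen after the genotype ratios and list medians had been seen, but before the value that each test measures was computed.

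The first pattern is the lower level of spiny neuron identity genes in Q175. Oligodendrocyte markers rose there (7 of 12, medians 0.43 in D1 and 0.55 in D2) and astrocyte markers went both ways (3 rose and 2 fell of 12). The astrocyte markers that fell, Slc4a4 and Atp1b2, stood at 278 and 53.1 CPM in D1 WT, where the list median was 3.65 CPM. Whether they reflect astrocytes was not tested. Medians in D1 and D2 were also above 0 for microglia (0.48 and 0.33), endothelial (0.19 and 0.33), GABA interneuron (0.07 and 0.93) and cortical excitatory markers (0.88 and 1.06). Mural markers stood at -0.11 and 0.74. Of these further lists, only the cortical one in D2 lay outside the random range (percentile 97.6). A lower share of the sorted neurons would raise markers of other cells, and most of these medians were above 0. It would also lower all genes enriched in that sort by about as much as the identity list. The 32 genes enriched in the D1 sort lay above the identity median by 0.44 (95% bootstrap interval 0.18 to 0.62). For the 33 genes enriched in the D2 sort the difference was 0.37 (0.10 to 0.73). But these genes were picked on the mean of the WT and Q175 ratios between the sorts. A gene that rose in the Q175 sort was thus more likely to be picked, which can raise both differences. The comparison therefore does not decide how much of the fall a lower share explains. A larger mitochondrial share of the Q175 libraries lowers all other genes alike by dilution. Scaled by library totals the mean of the identity medians was -0.55, and by totals without mitochondrially encoded genes -0.49 (-0.57 to -0.37). Dilution thus made up little of the fall, and this scaling cannot address what raised the mitochondrial share. Against length or GC content, the mean of the identity medians stayed at -0.68 (-0.75 to -0.55) after correction for both. A fall within the spiny neurons, a batch shared by both Q175 libraries and an EGFP gate that follows Drd1 and Drd2 expression were not tested and stay open, since the design does not separate them.

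The second pattern is that genes beside Drd1 and Drd2 differed between the sorts, among them Sfxn1, Ankk1, Ttc12, Tmprss5 and Hrh2. A candidate explanation is that the reporter transgenes carry flanking genes. The neighbours of Drd1 and Drd2 leaned to the matching sort by 1.21 log2 units more than the neighbours of other markers, but the 95% bootstrap interval ran from -0.03 to 7.01. Upb1 beside Adora2a and Il20ra beside Slc35d3 leaned in the same way without lying beside a reporter gene, so transgene copies and regulation shared between neighbouring genes cannot be told apart with so few genes.

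The third pattern is a cluster of genotype changes around Htt. Of the 40 nearest tested protein-coding genes, 18 passed the shared test (45%), against a median of 29.4% and a 95th percentile of 42.5% around 1000 random genes. This is consistent with a strain segment carried along with the knock-in allele, and Grk4 (1.29), Dok7 (1.08), Nop14 (0.67), Acox3 (0.59) and Mfsd10 (0.49) rose while D5Ertd579e (-0.74) and Add1 (-0.34) fell. Fgfr3 (0.84), counted above as an astrocyte marker that rose, is also among the neighbours that passed. Local regulation by the altered allele was not tested and stays open, and sequence variants could not be checked in count tables. The share lay at percentile 96.3 of the random genes, so a cluster of this size is uncommon there but not absent.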
